A study of Mus musculus with 5 samples.

How the data were processed

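Poly(A) RNA of sorted mouse CD4 T cells was reverse transcribed with an oligo-dT probe carrying a 7-base sample barcode and an 8-base molecular identifier, per the labels' protocols. FastQC, STAR 2.5.1a and the mm10 build are named in the submitters' processing notes, and the counting step is not given in the sources used here. The deposited tables hold whole-number counts, with a gene per line and 384, 382, 382 and 379 barcode columns for the colon control, colon light, lymph node control and lymph node light libraries. The lymph node tables end in a line without a gene name that repeats the column totals, equal to 50.0% of all counts in the table, and it was left out. Gene names were matched to GENCODE M21 on mm10 for 10136 of 10291 genes, and coordinates are from that annotation.

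Columns of a table were found to be overlapping sums of the same molecules. Each gene was written as a non-negative sum of column patterns shared by several genes, which was exact for 93.1%, 97.6%, 93.9% and 99.1% of genes in the 4 libraries and for 0 of 300 lines whose values were moved between columns. The exactly solved genes hold 43.1%, 49.9%, 58.6% and 94.5% of summed counts, and of 300 distinct lines drawn before the values were moved, 81.7%, 94.7%, 85.7% and 98.0% were exact. A molecule was counted in 59.9, 39.4, 79.4 and 40.2 columns on average. Summed counts were divided by the size-weighted number of columns per molecule (70.0, 49.9, 84.3 and 50.5), which gives molecule-equivalents. Columns are therefore neither cells nor replicates, and no clustering was run. On a simulated lymph node control library of 2760 genes, the patterns recovered the true total of 100.0% of exactly solved genes, and the weighted number of columns was 83.1 against a true 82.9.

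A barcode sheet of the pooled sample names 16 barcodes as replicates. None of the 16 is a column of the colon control table (0 of 16), all 16 are columns of each other table, and barcodes of a table's own group did not stand out. Their mean totals were 5239 against 5052 for the other groups' barcodes in the colon light, 2542 against 2510 in the lymph node control and 2640 against 2889 in the lymph node light library. The sheet was not used to form replicates, and the replicate tests planned in case it could be were not run. With 1 library per group no p-value was computed.

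The same gene's values were compared between tables by column position. A gene with a correlation above 0.5 was taken as repeated and was left out of each library whose column patterns missed its line by more than 0.4 of its size. This rule was set after the repeats were seen. It left out Foxp3 in all 4 libraries and Cd3d, Cd3e, Cd3g and Cd4 in the colon control, and these genes were also removed from that library's total.

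The log2 ratio of CPM (a gene's count scaled to a library total of 1e6) was computed with a prior count of 0.5 scaled to depth, for genes with at least 20 molecule-equivalents over the libraries compared, and a size limit of 2-fold was used. Planned intervals on the summed counts would have counted molecules repeatedly, so the exact 95% interval was taken on molecule-equivalents. For the difference of the light ratios, a normal interval on the log scale was used. In 200 simulations of light against control in the lymph node, with 200 changed genes, intervals covered the true ratio for 96.6% of unchanged genes (132 per simulation), 96.6% of genes changed 2-fold and 97.3% of genes changed 4-fold. The floor of 3 molecule-equivalents corresponded to 482, 76.3, 260 and 142 CPM. The shallow colon control therefore has the widest intervals.

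Named genes were, per comparison, up to 8 highest and 8 lowest by the interval end nearest to 0 among those whose interval excluded 0, leaving out unnamed gene models, pseudogenes, mitochondrial, ribosomal protein, haemoglobin and receptor segment genes, plus members of the gene lists described. The 34 gene lists, the rule for named genes and the comparisons were fixed in advance as well. A list's median and its percentile among 10000 random lists of the same size matched on expression in 5 bins were computed where at least 3 members passed the filter. The ratio of summed counts was computed for every list with a count. The Results give the median for some lists and the summed ratio for others, also for some lists that had a median. Shares of marker lists of other cell types carry Clopper-Pearson intervals. Other choices of scaling, total, filter, prior, depth and barcodes were set before the data were examined (10 of them), and 5 more were chosen after seeing the data: lists without the member of largest count, the repeated lines as deposited, each recovered molecule counted once, the deposited sums taken as raw counts, and totals without the 45S, Gm12374 and mitochondrial ribosomal RNA genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.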

Results

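CD4 T cells were sorted from the colon and from a lymph node of mice with colitis, and their poly(A) RNA was sequenced from the 3' end with sample barcodes and molecular identifiers. Treated mice were exposed to 980 nm laser light at 1.22 W and 80% duty over a spot of 4 square centimetres, for 5 minutes every 2 days. The groups were colon control, colon light, lymph node control and lymph node light, with 1 library each, so no difference below has a replicate check and no p-value is given. A further pooled sample held only a barcode sheet and entered no comparison. The deposited counts summed to 435847 in the colon control, 1959296 in the colon light, 971227 in the lymph node control and 1068864 in the lymph node light library. Barcode columns shared molecules, so these sums stood for about 6223, 39293, 11524 and 21151.5 independent counts (molecule-equivalents). Intervals are 95% Clopper-Pearson intervals on molecule-equivalents and cover counting error only.

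Cd3d, Cd3e, Cd3g and Cd4, which encode the CD3 chains and the CD4 co-receptor that define these cells, could not be measured in the colon control library. Their rows in the colon control table equalled those in the lymph node control table at 382 of 382 column positions, although 0 of those positions carried the same barcode. Cd3d summed to 984 in the colon control and 977 in the lymph node control, the difference lying in columns beyond the positions compared. No other gene listed in both control tables, apart from Foxp3, had a correlation by position above 0.143. The 4 rows missed the colon control's own column patterns by 0.453 or more of their size, and those of the lymph node control by 0.0364 or less. Foxp3, the transcription factor of regulatory T cells, had similar rows in all 4 tables, with correlations by position from 0.700 (colon light against lymph node light) to 0.979 (the control libraries). Most equal positions held 0 in both tables: of 382 positions 381 were equal between the controls, where 22 were above 0, and of 379 positions 363 were equal between the light libraries, where 36 were above 0. The unnamed last line of the lymph node tables equalled the column totals without Foxp3 in 99.7% of control columns and 100.0% of light columns, against 94.0% and 91.6% with Foxp3 counted. Foxp3 was therefore left out everywhere, and Cd3d, Cd3e, Cd3g and Cd4 were left out wherever the colon control was compared.

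**Figure D1:**
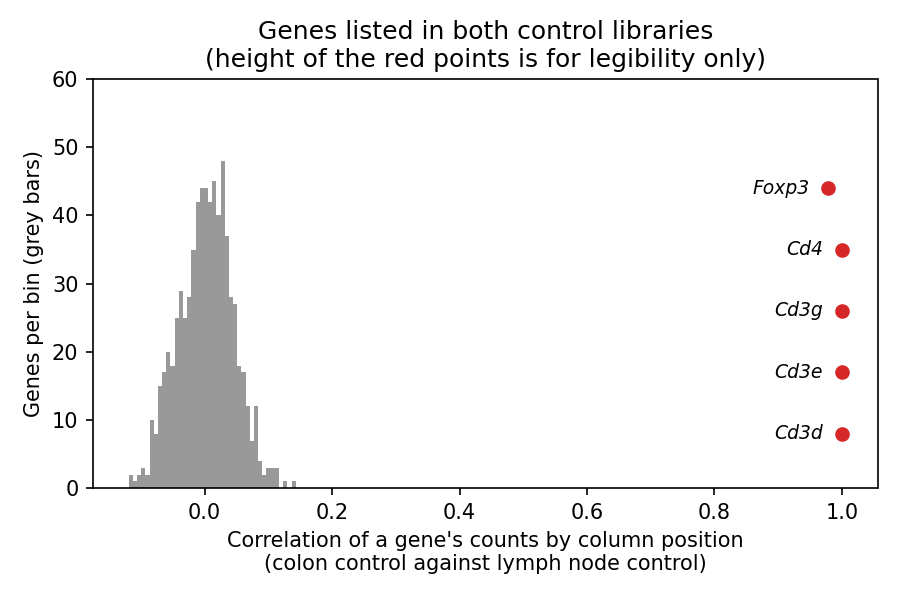
Correlation of each gene's counts between the colon control and lymph node control tables, column position by column position; grey bars count genes per bin and red points mark the 5 genes above 0.5, their height having no meaning. Cd3d, Cd3e, Cd3g and Cd4 lie at 1, Foxp3 at 0.979, and the other genes at 0.143 or below.

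Without those rows the colon control library held few T-cell transcripts. The T-cell identity genes together came to 5.24 molecule-equivalents there, against 120 in the lymph node control over the same members. Trbc2, a constant segment of the T-cell receptor beta chain, stood at 108 CPM in the colon control and 3592 CPM in the lymph node control. The library was led by the long noncoding RNA gene Gm12374, on chromosome 4 at 37249403 to 37332515 (mm10), with 17.6% of counts against 2.47%, 2.45% and 0.299% in the colon light, lymph node control and lymph node light libraries. Genes with a count in the colon control alone took 26.8% of its counts, while each other library gave 5.09% to 6.69% to genes of its own. The colon control shared at most 5 barcodes with any other library, and the others shared at least 373 with one another. These facts stand beside every comparison that uses the colon control.

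The comparison of light with control in the lymph node addressed the effect of 980 nm light on CD4 T cells there. Ccl5, a chemokine of effector and cytotoxic T cells, was lower after light, at 9814 against 25735 CPM (log2 ratio -1.39, interval -1.65 to -1.13). Ifi27l2a, an interferon-inducible gene, was lower by -1.21 (-1.80 to -0.65), and Ltb, which encodes lymphotoxin beta, by -1.74 (-3.36 to -0.44). Plac8 had a ratio of -1.36 (-2.42 to -0.41), Tspo of -1.41 (-2.80 to -0.20) and Lsp1 of -1.32 (-2.70 to -0.11), while Tmsb10 at -0.94 and Fau at -0.64 stayed under 2-fold. Nphp4, a ciliary gene on chromosome 4 at 152476706 to 152563183, was higher at 4828 against 1147 CPM (2.04, 1.24 to 3.02). Prkcsh was higher by 1.36 (0.50 to 2.38) and Ptprc, which encodes the leukocyte antigen CD45, by 1.14 (0.08 to 2.42). Blmh was higher by 1.13 (0.11 to 2.36), Nrg2 by 1.07 (0.03 to 2.33) and Sec61b by 1.76 (0.003 to 4.55). Sec61b rested on 2.57 molecule-equivalents in the control, under the floor of 3. Tmbim4 was 1.96-fold higher.

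Lower gene groups in the lymph node were carried largely by single genes. The Th1 list had a summed log2 ratio of -1.26 (-1.50 to -1.02) and the cytotoxic list of -1.22 (-1.47 to -0.98), but without Ccl5, which belongs to both, they stood at -0.41 (-1.10 to 0.30) and 0.18 (-0.63 to 1.06), and Ifng at -0.91 and Nkg7 at 0.43 had intervals that included 0. Interferon-response genes summed to -0.57 (-0.97 to -0.17), and without Ifi27l2a to 0.11 (-0.49 to 0.73), with Ifi203 at 0.63 (-0.76 to 2.30). Glycolysis genes summed to -0.90 (-1.60 to -0.22), and without Gapdh to -0.88 (-1.72 to -0.08). Mitochondrially encoded respiratory genes summed to 0.74 (0.17 to 1.36), with mt-Co1 at 1.19 (-0.39 to 3.37) and mt-Nd1 at 0.78 (-0.08 to 1.74), and without mt-Nd1 to 0.71 (-0.07 to 1.57), whereas nuclear genes of complex IV summed to -0.28 (-0.70 to 0.15). Ribosomal RNA was higher as well: the 45S gene CT010467.1 took 15.3% of counts after light against 10.5% (0.55, 0.45 to 0.65), and the mitochondrial ribosomal RNA mt-Rnr2 was higher by 0.94 (0.71 to 1.17). The other mitochondrial ribosomal RNA, mt-Rnr1, at 0.38 (-0.19 to 0.98), had an interval that included 0. T-cell identity genes had a median of -0.23 over 7 members, at percentile 46.3 of 10000 random lists matched on expression. The heat-shock list at -0.09 and the TRP channel and calcium list at -0.28 had intervals that included 0. B-cell and plasma-cell markers were lower at -2.22 (-4.45 to -0.67), on 4.10 against 11.7 molecule-equivalents, and without Igkc at -1.68 (-3.99 to 0.06). Of 188 genes with at least 20 molecule-equivalents, 10 were at least 2-fold higher and 11 at least 2-fold lower after light, around a median of -0.16. In simulations of this comparison 5.79% of unchanged genes reached 2-fold from counting error alone. With median-of-ratios scaling the split became 16 higher and 8 lower.

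**Figure D2:**
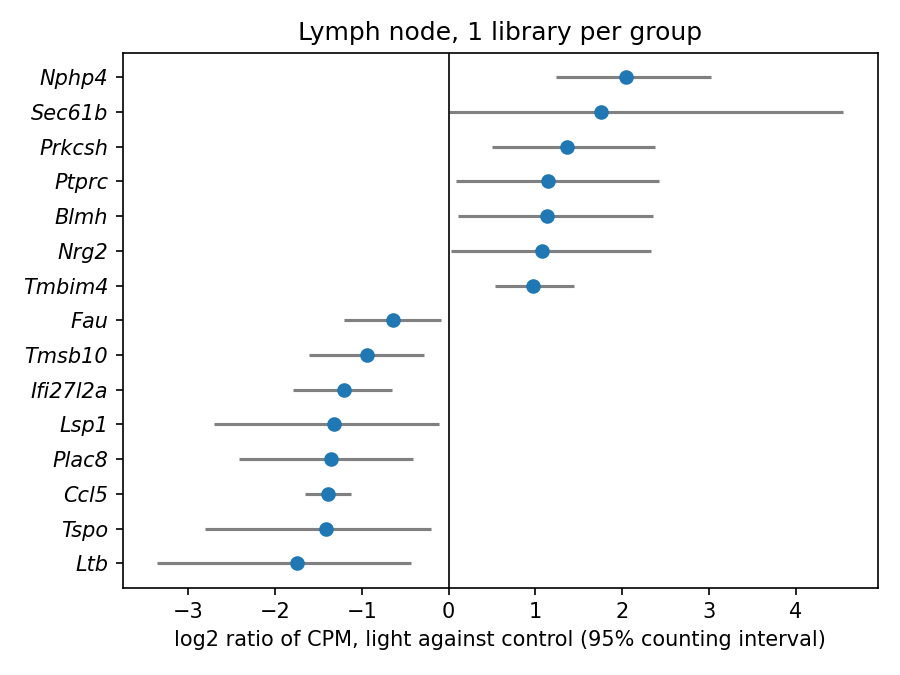
Log2 ratio of CPM, light against control, for the named lymph node genes, with 95% counting intervals as horizontal lines and 1 library per group. Nphp4 lies at 2.04, and Ccl5, at -1.39, has the narrowest interval below 0.

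The comparison of light with control in the colon compared 2 libraries of different content. Of 209 genes tested, 157 were at least 2-fold higher and 31 at least 2-fold lower in the light library, and the median log2 ratio was 2.16. Among the higher genes, Actb had a ratio of 3.20 (2.03 to 4.80), Fth1, which encodes ferritin heavy chain, of 4.84 (2.04 to 13.95), Ccl5 of 2.37 (1.29 to 3.79) and Malat1 of 2.05. Tmbim4, Nphp4 and Prkcsh were listed at 0 in the control and were at least 7.12-fold, 3.68-fold and 3.08-fold higher, against a floor of 3 molecule-equivalents per library. Such folds leave out the counting error of the other library, and the interval ends nearest to 0 were log2 2.51, 1.54 and 1.28. Among the lower genes, Tgm6, Cfap44, Pomk, Sema6a and Vmn1r189 were listed at 0 after light and were at least 394-fold, 342-fold, 215-fold, 179-fold and 94.5-fold lower against that floor, with interval ends nearest to 0 of -8.31, -8.10, -7.43, -7.15 and -6.20. Trpc7, a calcium-permeable channel, was lower by -7.34 (-8.71 to -6.48), Lrig2 by -8.55 (-12.18 to -7.19) and Tet1 by -7.54 (-14.74 to -5.84). Lrig2 and Tet1 rested on 1.97 and 0.842 molecule-equivalents after light, and Fth1 on 0.571 in the control, under the floor of 3.

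Of 33 gene lists with a count in the colon, 17 had intervals above 0, 2 below 0 and 14 including 0, and 28 intervals included the median of 2.16. That median covers genes with at least 20 molecule-equivalents over both libraries, which differ in depth, whereas list sums were not filtered. It was 1.48 with no count filter and -2.52 with the deeper library thinned, so a list's place against it depends on these settings. T-cell identity genes summed to 2.29 (1.10 to 3.92), and with the repeated rows taken as deposited the same list gave -0.24. Ribosomal protein genes had a median of 2.26 over 26 members, at percentile 59.3, and heat-shock genes of 2.19 over 5 members, at percentile 50.2. Immediate early genes summed to 2.75 (1.21 to 5.14), NF-kB and inflammatory genes to 1.99 (0.77 to 3.63) and myeloid markers to 2.00 (0.65 to 3.89), whose interval included 0 without Lyz2 (-0.02 to 3.73). The regulatory TGF-beta and IL-10 list was lower at -3.04 (-4.04 to -2.18), set by Smad4 at -5.54, and without Smad4 it turned to 4.30 with an interval that included 0. Naive and central memory genes at -0.35 (-1.49 to 0.97), Th2 genes at -0.60 (-2.08 to 1.15) and interferon-response genes at 0.79 (-0.26 to 2.08) also had intervals below the median. Natural killer and innate lymphoid markers, at -2.35 (-4.57 to -0.44), rested on Il1rl1. Median-of-ratios scaling gave 69 genes higher and 50 lower, around a median of 0.32, and thinning the deeper library turned the split to 18 higher and 24 lower, around a median of -2.52 over 44 genes.

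Control libraries of the colon and the lymph node were compared to describe the tissues without light. Ccl5 was lower in the colon by -4.54 (-6.00 to -3.52), Actb by -3.70, Malat1 by -3.00, Ifi27l2a by -4.69 (-10.82 to -2.53) and Trbc2 by -4.47 (-12.65 to -2.08). Ifi27l2a and Trbc2 rested on 0.928 and 0.671 molecule-equivalents in the colon control, under the floor of 3. Tmbim4, Ly6a and Zmynd8 were listed at 0 in the colon and were at least 9.48-fold, 7.52-fold and 4.58-fold lower against the floor, with interval ends nearest to 0 of -2.90, -2.55 and -1.79. Tgm6, Lrig2, Cfap44, Pomk, Sema6a, Tet1 and Vmn1r189 were listed at 0 in the lymph node and were at least 115-fold, 104-fold, 100.4-fold, 63.2-fold, 52.4-fold, 31.0-fold and 27.7-fold higher in the colon against the floor. Their interval ends nearest to 0 were 6.54, 6.38, 6.34, 5.66, 5.38, 4.60 and 4.43, and Trpc7 was higher by 7.49 (5.95 to 11.41). Trpc7 rested on 1.70 molecule-equivalents in the lymph node control, also under the floor. The T-cell identity list summed to -3.54 (-5.22 to -2.39), the Th1 list to -4.18 (-5.35 to -3.31), or -2.44 (-4.99 to -0.87) without Ccl5, and the ribosomal protein list to -2.64 (-3.05 to -2.27). Of 89 genes, 26 were at least 2-fold higher and 60 at least 2-fold lower in the colon, with a median of -2.18. Median-of-ratios scaling turned this to 31 higher and 17 lower, and a filter of at least 100 molecule-equivalents to 7 higher and 5 lower, around a median of 2.39.

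The light-treated libraries allowed the tissues to be compared without the colon control. Ms4a4b, a membrane protein of T cells, was lower in the colon, at 248 against 2672 CPM (-3.35, -4.58 to -2.44). Ly6a was lower by -2.06, Ifi27l2a by -1.95, Ly6c2 by -2.36, Ifi203 by -2.29, Zmynd8 by -1.84 and Tmbim4 by -1.38. T-cell identity genes had a median of -1.64 over 7 members, at percentile 0.02 of the matched random lists, including Trac at -2.36, Cd3d at -1.65 and Lat at -1.64. Naive and central memory genes summed to -1.91 (-2.52 to -1.36), and without Ms4a4b to -0.53 (-1.38 to 0.32), gut-homing genes to -1.81 (-2.84 to -0.92) and interferon-response genes to -1.37 (-1.80 to -0.97). The interval of each of these lists in full included the T-cell identity median of -1.64, which is a median over members and not a sum. On summed counts, T-cell identity genes without Trbc2 stood at -1.22 (-1.54 to -0.91). The gut-homing and interferon-response intervals included that ratio too, so neither list was shown to be lower than T-cell identity genes in general. The naive and central memory interval lay below -1.22 but overlapped its interval, and the list's place rested on Ms4a4b.

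Immediate early, inflammatory and class II antigen presentation genes and myeloid markers were higher in the colon light library. The activation and effector list took 0.153% of counts there (0.117 to 0.197) against 0.0837% in the lymph node light library. Without Tnfrsf4 its ratio was 0.64 (-0.21 to 1.60). Which cells carried any of these genes was not tested. Immediate early genes summed to 2.71 (1.84 to 3.82), with Jun at 2.16, and NF-kB and inflammatory genes to 1.93 (1.24 to 2.74), with Il1b at 3.07 (0.96 to 7.99) and Nfkbia at 1.76. Cd74 at 3.18 (1.02 to 8.46), H2-Eb1 at 3.33 (1.00 to 9.95) and H2-Ab1 at 2.57 (0.49 to 6.92), all of the class II antigen presentation pathway, placed the B-cell and plasma-cell list at a median of 3.18, at percentile 99.96. Myeloid markers summed to 1.44 (0.77 to 2.20), with Lyz2 at 1.97 and Fcer1g at 1.77 (0.03 to 4.55). Tissue-residency genes summed to 1.16 (0.30 to 2.15), and without Rgs1 to 0.65 (-0.26 to 1.67). Snord49b stood at 805 against 47.7 CPM, and Hnrnpd was higher by 3.18 (1.48 to 6.35), Mir6236 by 2.97 (1.37 to 5.73), Cdk14 by 2.91 (1.35 to 5.56), Grk6 by 2.93 (1.06 to 6.64) and Ank2 by 3.05 (0.97 to 7.78). Snord49b, Hnrnpd, Mir6236, Cdk14, Grk6 and Ank2 rested on 1.01, 2.12, 2.55, 2.71, 1.72 and 1.27 molecule-equivalents in the lymph node light library. Cd74 and H2-Eb1 rested on 1.11 and 0.851 there, and Jun on 2.95. All of these lie under the floor of 3, which is 142 CPM in that library. Ribosomal RNA and heat-shock genes were also higher there: the 45S gene CT010467.1 took 28.4% of counts against 15.3%, mitochondrial ribosomal RNA 7.05% against 3.82%, and heat-shock genes summed to 0.42 (0.09 to 0.77), or 0.62 (0.21 to 1.05) without Hsp90ab1. The B-cell and plasma-cell list took 0.201% of counts in the colon light library (0.159 to 0.251) against 0.0194% in the lymph node light library. In the colon light library 5 of its 19 genes had a count. Cd74 and H2-Eb1 held 23.9 and 21.8 of its 79.0 molecule-equivalents there. The share thus rests largely on class II genes and does not single out B cells. Myeloid markers took 0.273% (0.224 to 0.330) against 0.0998%. Of 303 genes, 41 were at least 2-fold higher and 58 at least 2-fold lower in the colon, around a median of -0.34, and median-of-ratios scaling gave 53 higher and 30 lower.

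**Figure D3:**
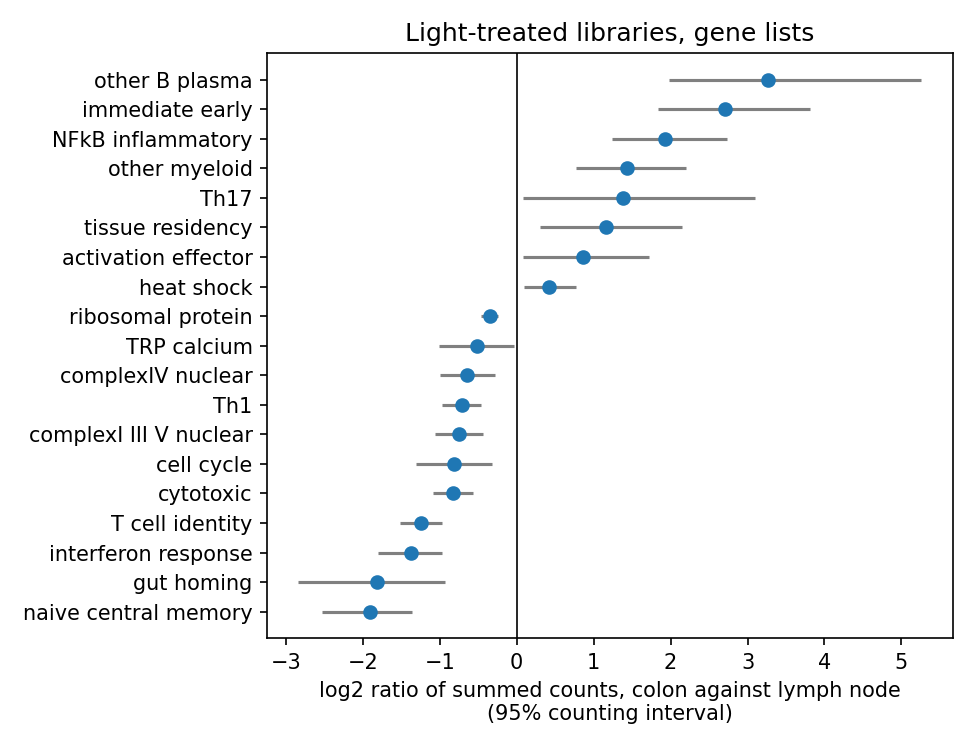
Log2 ratio of summed counts, colon against lymph node, in the light-treated libraries, for the gene lists whose 95% counting interval (lines) excluded 0. The B-cell and plasma-cell list, led by the class II pathway gene Cd74, lies highest at 3.27, and naive and central memory genes lowest at -1.91.

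The difference of the light ratios between the tissues carried the content of the colon control. Ccl5 differed by 3.76 (2.65 to 4.88), Actb by 3.18 and Fth1 by 5.07 towards the colon, and Trpc7 by -7.68, Otub2 by -5.87 and Sfswap by -3.35 towards the lymph node. Fth1 rested on 0.571 molecule-equivalents in the colon control, and Trpc7 and Otub2 on 1.70 and 2.92 in the lymph node control. These values lie under the floor of 3. Snord49b, Tmbim4, Sub1, Eif2s2 and Ssb were listed at 0 in the colon control, and Lrig2, Sema6a, Tgm6, Cfap44 and Pomk in at least 1 of the other libraries, so no fold is given for them. Of 411 genes, 309 differed by at least 2-fold towards the colon and 39 towards the lymph node, with a median of 2.45. Median-of-ratios scaling gave 170 and 102.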

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

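The genes below were picked out because their counting intervals lay on opposite sides of 0 in the colon and in the lymph node, a comparison made after the results were seen. Each value is the log2 ratio of light against control in the colon minus that in the lymph node, and the difference was not tested, as each group had 1 library. Ccl5 differed by 3.76, B2m by 3.20, Actg1 by 2.69, Malat1 by 2.42 and Fau by 1.83. In the lymph node Ccl5 stood at -1.39, B2m at -0.67, Actg1 at -0.68, Malat1 at -0.37 and Fau at -0.64. All 5 were higher in the colon light library, where the median gene was higher by 2.16 than in a colon control library with few T-cell transcripts of its own. B2m and Actg1 rested on 1.43 and 2.38 molecule-equivalents in the colon control, under the floor of 3. With median-of-ratios scaling the colon median was 0.32 and the colon intervals of all 5 included 0, with Ccl5 at 0.53, B2m at 0.69, Actg1 at 0.17, Malat1 at 0.21 and Fau at -0.65, so none of the 5 had intervals on opposite sides of 0 with that scaling. In the lymph node that scaling left only Ccl5 below 0, at -1.23 (-1.49 to -0.97). The lymph node intervals of B2m, Actg1, Malat1 and Fau then included 0, as they did with TMM.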

How the results depend on the processing

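Numbers of genes at least 2-fold higher or lower moved most with the count filter and with raw sums. Their split shifted with the scaling, with thinning of the deeper library, with the stricter filter and, between light tissues, with the total. In the colon, light against control gave 157 higher and 31 lower in the analysis reported, and 119 in all (69 and 50) with median-of-ratios, 122 (78 and 44) with TMM, 42 (18 and 24) with the deeper library thinned, 4557 with no filter, 25 with at least 100 counts and 7316 with the deposited sums as raw counts. In the lymph node 10 and 11 became 24 (16 and 8) with either scaling, 2739, 4 and 5381 with no filter, the stricter filter and raw sums. Between control tissues 26 and 60 became 48 (31 and 17), 49 (31 and 18), 54 (25 and 29) when thinned, 2678, 12 and 4935. Between light tissues 41 and 58 became 83 (53 and 30) with either scaling, 83 (55 and 28) without the 45S, Gm12374 and mitochondrial ribosomal RNA genes, 64 (18 and 46) when thinned, 3481, 5 and 6543. The difference of light ratios, 309 and 39, became 272 (170 and 102), 274 (181 and 93), 119 (93 and 26) when thinned, 5356, 61 and 9008. With the repeated lines as deposited, the T-cell identity list turned to -0.24 in the colon and -0.12 in the difference. With median-of-ratios and TMM in turn, lists that changed direction were, in the colon, nuclear complex I, III and V (-0.19, -0.0192), apoptosis (-0.56, -0.38) and B-cell markers (-0.0733, median-of-ratios). Between control tissues they were naive and central memory (1.15, 1.13), heat shock (0.35, 0.33), mitochondrially encoded (0.41, 0.38), TRP and calcium (0.86, 0.84) and cell cycle (0.75, 0.73). In the difference they were interferon response (-0.64, -0.47), nuclear complex I, III and V (-0.19, -0.0203) and mitochondrially encoded (-0.13, median-of-ratios), and thinning turned the TGF-beta and IL-10 list to 0.59. Without the member of largest count, a choice made after seeing the data, the TGF-beta and IL-10 list turned to 4.30 in the colon, -2.68 between control tissues and 4.20 in the difference, natural killer markers to 2.88 in the colon, the cytotoxic list to 0.18 in the lymph node and the naive and central memory list to 0.0869 between control tissues. Of 2270 other values 2102 stayed inside the counting interval of the reported analysis, 139 moved outside it and 29 of at least 2-fold reversed in sign. Some of these intervals were wide or unbounded. The looser and stricter count filters (158 and 114 same) could not change a ratio. Nor could the limit of 500 counts per barcode (158 same), as every column held at least 917. Leaving out the deepest barcode and averaging over barcodes (157 same each) could change little, as molecules lay in many columns of similar totals. The pooled count of values that stayed thus says little about scaling. Median-of-ratios left 92 the same, moved 55 and reversed 11, and TMM left 96 the same, moved 53 and reversed 9. No paired analysis was possible because each group had 1 library and no animal was named across groups. Tests on replicates, leaving out replicates and a replicate block were not run for the same reason.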

Other observations

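The explanations in this part and their tests were chosen after the results were seen, although median-of-ratios, TMM and the total without mitochondrial, ribosomal protein and immunoglobulin genes were set as other scalings before the data were examined.

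The repeated gene lines bear on the use of Foxp3 in every library and of Cd3d, Cd3e, Cd3g and Cd4 in the colon control. The same Cd3d, Cd3e, Cd3g and Cd4 lines in both control tables do not come from the same library under both names, as no other shared gene but Foxp3 correlated above 0.143 by column position. The 4 lines missed the colon control's column patterns by at least 0.453 of their size, which suggests that they were carried from the lymph node control table into the colon control table. The unnamed total equalled the column totals without Foxp3 in at least 99.7% of columns, in line with a Foxp3 line added after the totals were made. How either came about cannot be read from the tables, and the submitters' original counts would settle it.

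The colon control library held other genes than the other libraries. Each of the 8 genes named as lower after light lay in at least 35 column patterns, so a few patterns are unlikely to explain them. The patterns were inferred, and exactly solved genes held 43.1% of the colon control's summed counts. How many barcodes stood behind these genes was thus not measured. With 29 genes out of both totals, those at least 2-fold higher in the colon control than in the colon light and lymph node control libraries plus Gm12374 and the 45S and mitochondrial ribosomal RNA genes, the median light ratio was 2.07. Taking them out could not have brought it below 1.18, so this left open whether a few genes taking the counts play a part. The colon control shared at most 5 barcodes with any other library, so another barcode set or batch and a true effect of the treatment cannot be told apart. Differences between light and control in the colon may thus reflect the library rather than the light.

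Ccl5 and Ifi27l2a were lower in the lymph node after light. Under 4 other scalings the highest upper interval end of either gene was -0.487, so scaling likely does not account for the difference. Both genes lay in at least 38 column patterns of the control library, so a few patterns likely do not either. The patterns were inferred and are not barcodes. Natural killer and CD8 markers came to 2.60 molecule-equivalents in the lymph node control, too few for fewer cytotoxic cells of another type to be told apart from lower expression in CD4 T cells. The cytotoxic list without Ccl5 was not lower with it, at 0.18 (-0.63 to 1.06), but each group had 1 library. Counting Ccl5 in replicate animals would separate chance between mice from an effect of light.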
